A study of Mus musculus with 191 samples.

How the data were processed

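RNA sequencing libraries from mouse bone marrow, gut, liver, lung and ear skin were compared. In the first 4 tissues, mice received anti-Ly6G antibody (clone 1A8), which binds a surface protein of mouse neutrophils, or control IgG, both at 3 µg per g for 2 days, and were collected on the third day. Each of these tissues had 18 libraries per treatment, 3 at each of the Zeitgeber times (ZT, hours after lights on) 1, 5, 9, 13, 17 and 21. Per the labels, some mice were kept in cabinets with light inverted by 12 h, and the labels do not say which, so an effect of the cabinets was not separated from ZT in the rhythms, peak times and clock shifts. Skin came from 3 genotypes at 16 ZT between 1 and 24, with 1 mouse per ZT and genotype. Control skin was labelled as from wild-type C57BL/6 mice given diphtheria toxin (DT), a label put in doubt by a low value of Gt(ROSA)26Sor. The iDTR mice carry a DT receptor that Mrp8CRE is meant to switch on in neutrophils, and received DT at 10 µg per kg for 2 days. Which skin cells carried the receptor was not measured. The Bmal1-flox mice carry Mrp8CRE with floxed Arntl (the gene for BMAL1, an activator of the core clock) and received no DT per the labels. Skin had 16 control, 16 iDTR and 15 Bmal1-flox libraries, the last without ZT 16.

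Per the labels, libraries were made from 200 ng of total RNA with the NEBNext Ultra kit, were not pooled between mice, and were read as 50 nt single reads on a HiSeq2500. The labels name mm10, CASAVA 1.8, cutadapt 1.7.1, RSEM 1.7.1, limma 3.46 and Ensembl build 84, while the extraction protocol names RSEM 1.2.20 and Kallisto 0.43.1. Neither states the normalization method or the gene filter of the tables.

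There was 1 table per tissue. The deposited values are a normalized signal on a linear scale. In every column they behaved as RSEM expected counts plus 0.5, divided by a scaled library size and multiplied to a per-million scale, since multiplying a column by 0.5 over its minimum gave values with at most 2 decimals. Whole numbers made up 29.7% of the recovered counts in lung and 44.5% in liver, the lowest and highest of the 5 tissues, so these are expected counts and not whole reads. The recovered totals were the depth used here, and 1 read equalled between 0.0319 and 0.131 units. The tables held 16335 genes in bone marrow, 17223 in gut, 14451 in liver, 17360 in lung and 18556 in skin. Symbols and GRCm38 coordinates came from GENCODE M21, matched by identifier, with 57, 57, 44, 68 and 75 identifiers unmatched in that order.

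Groups were taken from the labels alone. Values were transformed as log2(value + 1) in R 4.3.3, and genes with a mean value of at least 1 over the tissue's libraries were tested. This left 14289 genes in bone marrow, 15158 in gut, 12504 in liver, 15641 in lung and 15946 in skin. Linear models were fitted with limma 3.58.1 and moderated with a mean-variance trend. All tests were two-sided, with Benjamini-Hochberg adjustment over the genes of a tissue and a threshold of 0.05. The treatment effect was adjusted for ZT as a factor, and the genotype effect in skin for a 24 h wave. Rhythms were tested in each group by an F test of a cosine and a sine with a 24 h period, with the residual spread shared by the groups of a tissue. A differential rhythm was the F test of the difference of those 2 terms between groups. Peak times are hours ZT, amplitudes are on the log2 scale, and folds of a rhythm are peak to trough. Transcripts are named by gene, and folds of a comparison are of log2(value + 1).

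Before the data were examined, 50 gene lists were fixed, holding core clock genes, markers of cell types, and pathways. Lists with at least 4 tested members were tested with limma's camera at a preset correlation of 0.01, with adjustment over the 246 tests of the 6 comparisons against a control, and again with an estimated correlation. Library means of 3 neutrophil lists were compared by permutation tests with 1e+05 exchanges of labels within ZT, adjusted over 14 tests. The rule for genes named in the text was fixed at the same time. It takes members of the core clock and neutrophil lists. It takes, for each comparison, the 8 largest rises and 8 largest falls past the threshold with the same sign at 5 or more of 6 ZT (in skin at 75% or more of ZT), without unnamed gene models, immunoglobulin and T cell receptor segments and small RNAs. It takes, for each group, the 6 smallest rhythm p-values outside the core clock. It takes, for each differential rhythm, the 8 smallest p past the threshold, or the 3 smallest where fewer than 3 passed. It takes, for each list past its test, up to 4 members past the threshold with the largest change, or the 3 largest stated not to pass. For the core clock genes as a set, the shift in peak time between groups was a mean over genes weighted by amplitude. It was tested by a permutation test chosen after the data were seen.

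Alternatives covered the pseudocount (0.1, 5 or none), no filter or a filter at a mean of 4, quantile normalization, array weights, voom weights, a robust trend, ZT as a factor in the rhythm tests, each group fitted alone, a minimum peak-to-trough range of 0.5 on the log2 scale, no time term, a block for replicate number, and leaving out each library and, in the antibody tissues, each ZT. In skin only ZT 16 was left out in all genotypes, for the rhythm tests. For counts of called genes, 100 assignments of labels or of ZT, the labelled one included, were fitted. Where more than 5% of genes differed in level between the groups, the counts of rhythms were also taken with each group's mean removed before the labels were exchanged. The functions were tested on simulated data with 200 changed genes of each kind. Per tissue, the tests recovered between 83.4% and 94.9% of the genes changed 1.5-fold, with between 3.84% and 5.33% of calls false, and between 78.0% and 88.0% of rhythms with an amplitude of 0.5, with between 4.47% and 6.59% of rhythm calls false. Simulated genes varied independently, with the same spread in all groups, and rhythms were scored in IgG or control only. No differential rhythm was simulated. These shares therefore do not cover variation shared by the genes of a library or a larger spread in iDTR. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. The kit's strand setting was not used. Ly6g was analysed in bone marrow, gut and liver, and is not analysed here in lung and skin. A pairing of mice across treatments was not used, since the labels give none. The random draws were made once before with the libraries sorted in another order. In those draws the groupings did not exclude chance for the differential rhythm of bone marrow, the highest other grouping of lung gave several times its labelled differential rhythms, and the mature neutrophil list of bone marrow passed the threshold narrowly, so these results depend on the draw.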

Results

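Gene expression was measured by RNA sequencing around the day in 5 mouse tissues, to ask how the daily transcription of tissues depends on neutrophils and on the neutrophil clock. In bone marrow, gut, liver and lung, 18 libraries from mice given anti-Ly6G were set against 18 from mice given IgG. In ear skin, 16 libraries from iDTR mice and 15 from Bmal1-flox mice were set against 16 control libraries. Depth, in recovered read counts (M, units of 1e+06), was between 13.7 and 23.4 M per library in bone marrow IgG and between 12.0 and 19.6 M in bone marrow anti-Ly6G. The ranges were 11.7 to 27.6 and 10.2 to 30.9 M in gut, 10.3 to 23.2 and 10.3 to 18.3 M in liver, and 11.5 to 21.2 and 14.2 to 20.4 M in lung, in the same order. In skin they were 10.3 to 17.6 M in control, 11.3 to 25.4 M in iDTR and 7.68 to 23.9 M in Bmal1-flox. Values below are group means ± SD of the normalized signal, and log2 differences carry their SE from limma.

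The first question was what anti-Ly6G did to bone marrow, the tissue in which neutrophils form. Ly6g itself (ENSMUSG00000022582, chromosome 15, 75155240 to 75159126), which encodes the antibody's target, had a mean of 104 with IgG and 118 with anti-Ly6G, a log2 difference of 0.16 (SE 0.0578; adjusted p = 0.0498). Prtn3, encoding proteinase 3 of the azurophil granules, which neutrophil progenitors load with proteases and myeloperoxidase (ENSMUSG00000057729, chromosome 10, 79874476 to 79883174), was 364 ± 53.1 with IgG and 581 ± 89.2 with anti-Ly6G (n = 18 each), 1.59-fold higher (log2 0.67, SE 0.0656; adjusted p = 9.1e-09). Il1b, encoding the cytokine interleukin 1 beta (ENSMUSG00000027398, chromosome 2, 129364570 to 129371139), fell from 40.6 ± 21.0 to 11.8 ± 3.36 (log2 -1.61, SE 0.144; adjusted p = 2.6e-09). Both had the same sign at 6 of 6 ZT.

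All 9 measured azurophil granule genes rose, among them Mpo (myeloperoxidase, log2 0.51), Elane (neutrophil elastase, 0.49) and Ctsg (cathepsin G, 0.56). The median log2 difference of the list was 0.48 (adjusted p = 8.4e-17; adjusted p = 0.067 with an estimated correlation). Of 18 genes of the later specific and gelatinase granules, 13 rose, or 16 adjusted over the list alone, and none fell, with Lcn2 at 0.32, Ltf at 0.27 and Ngp at 0.27. Their median was 0.24 (adjusted p = 4.5e-11; adjusted p = 0.439 with an estimated correlation). S100a8 and S100a9, abundant alarmins of mature neutrophils, were at 0.15 (adjusted p = 0.139) and 0.11 (adjusted p = 0.303). Of 23 mature neutrophil genes, 9 rose and 3 fell, or 12 and 3 adjusted over the list alone (adjusted p = 0.00706; adjusted p = 0.719 with an estimated correlation). Cd177 was at 0.36 and Slfn4 at 0.38, the G-CSF receptor gene Csf3r fell to -0.23, and the chemokine receptor gene Cxcr2 was at 0.02 (adjusted p = 0.882). As library means, the azurophil list was 1.38-fold and the specific granule list 1.17-fold higher, each with a permutation p = 1e-05, the smallest these permutations can give (adjusted p = 7e-05). The mature list was 1.078-fold higher, with a permutation adjusted p = 0.0503 at the edge of the threshold, and 0.00849, 0.0407 and 0.343 with a pseudocount of 5, after quantile normalization and with a pseudocount of 0.1.

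**Figure D1:**
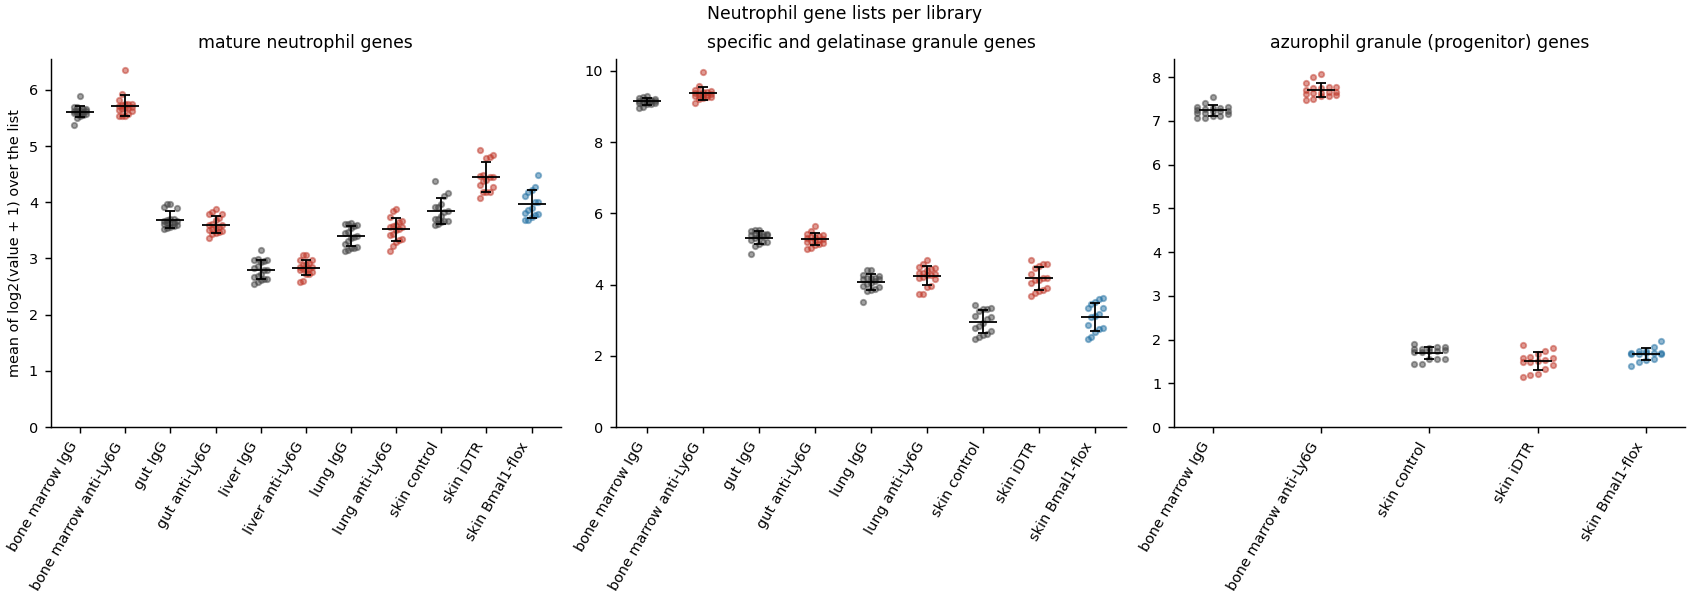
Mean log2(value + 1) of the members of 3 neutrophil gene lists (vertical axes) in each library (points) by tissue and group (horizontal axis), with the group mean and SD in black. In bone marrow the specific granule list had a mean of 9.37 with anti-Ly6G and 9.14 with IgG, and in skin it was 4.18 in iDTR and 2.96 in control.

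Of 14289 genes tested in bone marrow, 1422 rose and 1023 fell. The largest rise was that of AY036118, which lies in a ribosomal RNA repeat and varied widely between libraries (1.19 ± 4.70 to 21.6 ± 32.3, log2 2.06, SE 0.521; adjusted p = 0.0051; 5 of 6 ZT). Besides Prtn3, other large rises included Ggt1 (gamma-glutamyltransferase, 1.98 to 4.62, log2 0.90), Vcan (the matrix proteoglycan versican, 0.81), the endothelial lipase gene Lipg (0.72), the clock gene Per1 (18.1 to 33.0, log2 0.72) and the stress gene Ddit4 (0.69). Besides Il1b, large falls included Ptgs2 (cyclooxygenase 2, log2 -1.17), the immediate early gene Fos (21.0 to 7.76, -1.16), the neutrophil chemoattractant gene Cxcl2 (-0.92) and the muscle creatine kinase gene Ckmt2 (-0.91). Of 15 immediate early genes 6 fell and 1 rose, with Junb at -0.47 and Dusp1 at -0.46 (adjusted p = 0.0013; adjusted p = 0.439 with an estimated correlation). Of 12 eosinophil and basophil genes 9 rose, among them Mcpt8 (0.35) and Siglecf (0.30), with adjusted p = 2.1e-05 and adjusted p = 0.160 with an estimated correlation. Of 16 B cell genes 12 fell and none rose, among them Igll1 (-0.50), Vpreb1 (-0.42) and Rag1 (-0.34), which serve B cell precursors (adjusted p = 3.9e-09; adjusted p = 0.439 with an estimated correlation). Of 15 erythroid genes 11 fell, with Car2 (carbonic anhydrase 2) at -0.24 (adjusted p = 2.2e-08; adjusted p = 0.439 with an estimated correlation). Of 11 hypoxia and glycolysis genes 8 rose and 1 fell, with Egln3 at 0.31 and the glucose transporter gene Slc2a1 at 0.29 (adjusted p = 6.4e-05; adjusted p = 0.439 with an estimated correlation). The skeletal muscle list had a median of -0.53 with 2 of 12 genes fallen (adjusted p = 0.0063; adjusted p = 0.719 with an estimated correlation). The number of called genes was 1394 without ZT 1. Over all comparisons against a control, 81 of 246 list tests passed with the preset correlation and 3 with an estimated correlation, namely glucocorticoid response in liver, and fatty acid synthesis and sebaceous gland and adipocyte genes in iDTR skin.

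Daily rhythms in bone marrow were asked about in each treatment. The clock repressor gene Nr1d2 peaked at 9.89 h (SE 0.39, 2.14-fold) with IgG and at 6.14 h (SE 0.319, 2.53-fold) with anti-Ly6G. Nr1d1, Dbp, Tef and Per3, targets of the clock's activators, peaked at 7.09, 10.2, 11.3 and 10.9 h with IgG, and at 4.85, 6.23, 7.77 and 8.05 h with anti-Ly6G. Per1 had an amplitude of 0.11 with IgG (adjusted p = 0.853) and 0.68 with anti-Ly6G (adjusted p = 0.0085). Of 18 core clock genes, 6 were rhythmic with IgG and 8 with anti-Ly6G, or 7 and 14 adjusted over the list alone. Outside the clock, the cold-induced RNA binding gene Rbm3 peaked at 7.91 h (1.87-fold) and the eosinophil chemokine receptor gene Ccr3 at 19.0 h (1.72-fold) with IgG, and the fatty acid desaturase gene Scd2 peaked at 16.6 h (1.88-fold) with anti-Ly6G. Over all genes Nr1d2 was the only one with a differential rhythm, and 5 of 18 core clock genes had one adjusted over the list alone (Nr1d2 at adjusted p = 0.000906; 0.127 without ZT 1 and 0.401 without ZT 13, the range over its alternatives being 0.000142 to 0.401). In all, 232 genes were rhythmic with IgG and 58 with anti-Ly6G, and 30 were in both sets, against 0.942 if the sets were independent. The groups of a tissue share 1 spread estimate per gene, which can place a gene in both sets. The numbers for independent rhythmic sets, here and in the other tissues, are therefore no test of the overlap. Which treatment had more was not stable, since the counts were 396 and 498 with ZT as a factor, 272 and 787 without ZT 1, and 24 and 39 without ZT 17. The IgG count was 104 without ZT 5, 147 without IgG replicate 4 and 359 without IgG replicate 6. The anti-Ly6G count was 33 without ZT 5, 27 without ZT 9 and 7 without ZT 21, and without anti-Ly6G replicates 1, 4, 5, 8, 15, 17 and 18 it was 147, 28, 36, 31, 38, 38 and 35.

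In gut, the same antibody comparison called 2 genes. Inpp1, encoding inositol polyphosphate 1-phosphatase (ENSMUSG00000026102, chromosome 1, 52785427 to 52817688), fell from 17.5 ± 2.42 to 14.8 ± 2.15 (log2 -0.23, SE 0.0366; adjusted p = 0.0038; n = 18 each). Gdpgp1, encoding a GDP-glucose phosphorylase (ENSMUSG00000050973, chromosome 7, 80232865 to 80242061), fell from 11.01 ± 2.35 to 8.70 ± 1.44 (log2 -0.30, SE 0.0528; adjusted p = 0.019). Both were lower at 6 of 6 ZT. Ly6g had means of 160.1 with IgG and 150.1 with anti-Ly6G (log2 -0.09, SE 0.0759; adjusted p = 0.655). With IgG, Cxcr2 was at 2.31 in gut and 145 in bone marrow, where Ly6g was at 104, so most of the Ly6g signal in gut was not a measure of neutrophils. The library mean of 6 genes of the mature neutrophil list, the most abundant of which in gut, Sorl1 and Slfn4, are not specific to neutrophils, was 0.939-fold with anti-Ly6G (3.602 ± 0.15 against 3.69 ± 0.144; permutation adjusted p = 0.00708), and that of 6 specific granule genes was 0.971-fold (permutation adjusted p = 0.452). No member of the lists below passed over all genes. Cholesterol biosynthesis genes had a median of -0.12 (adjusted p = 8.1e-06; adjusted p = 0.577 with an estimated correlation), with 1 of 19 lower adjusted over the list alone, and Sqle and Cyp51 at -0.20 and -0.18. Goblet and enteroendocrine genes had 4 of 11 lower adjusted over the list alone (adjusted p = 0.00025; adjusted p = 0.448 with an estimated correlation), with the mucus gene Clca1 at -0.22. Mitotic genes, with Top2a at -0.18, passed at adjusted p = 0.0027 (adjusted p = 0.719 with an estimated correlation). Smooth muscle genes, with the myosin gene Myh11 at 0.16, passed upwards at adjusted p = 0.0077 (adjusted p = 0.615 with an estimated correlation). Of the anti-Ly6G libraries, replicate 1 carried transcripts of the seminal vesicle (Svs5 at 12477) and prostate (Pbsn at 357) and replicate 6 pancreatic ones (Prss2 at 85.9), and IgG replicate 10 had Pbsn at 40.1. Without those 2 anti-Ly6G libraries treatment called 2 genes, and 5331 genes were rhythmic with IgG and 2987 with anti-Ly6G.

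Both gut calls ended without ZT 5 (adjusted p = 0.069 each), with a block for replicate number (adjusted p = 0.123 each) and with no time term (adjusted p = 0.654 each). The count was 4, 18, 16 and 44 without IgG replicates 2, 4, 9 and 3, and 12, 4, 37, 33, 5 and 19 without anti-Ly6G replicates 2, 4, 5, 7, 12 and 13, and voom weights gave 41. It was 22 without ZT 1, 16 without ZT 13, 1 without ZT 9 and 1 without ZT 21.

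Rhythms in gut were strong in both treatments. The clock output gene Dbp peaked at 10.1 h (SE 0.23, 59.9-fold) with IgG and 9.68 h (SE 0.226, 64.5-fold) with anti-Ly6G, and Arntl at 23.3 h (3.49-fold) and 22.6 h (4.09-fold). Nr1d1 peaked at 8.38 and 7.63 h, and Per2 at 15.1 and 14.7 h. The cell cycle gene E2f2 peaked at 22.2 and 22.1 h, the glycolysis gene Pgk1 at 16.4 and 16.6 h, and the clock-interacting gene Cipc at 11.5 and 10.5 h. Of 19 core clock genes 18 were rhythmic with IgG and 17 with anti-Ly6G, or 18 and 18 adjusted over the list alone, Rora being called in neither. With IgG 5091 genes were rhythmic and with anti-Ly6G 3725, of which 2659 were shared, against 1251 if independent. No gene passed the differential rhythm test in limma, with 984 at an unadjusted p under 0.05 and 0 by voom weights. The smallest p-values, which did not pass, were those of Rsc1a1, Gm36371 and H6pd (adjusted p = 0.264 each), and the count was 1 without anti-Ly6G replicate 8 and 1 without ZT 5.

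In liver, Saa3, encoding an acute phase serum amyloid A protein (ENSMUSG00000040026, chromosome 7, 46711998 to 46715700), rose from 3.41 ± 2.04 with IgG to 8.16 ± 4.16 with anti-Ly6G (log2 1.07, SE 0.16; adjusted p = 0.00045; n = 18 each). Tsc22d3, a target of the glucocorticoid receptor (ENSMUSG00000031431, chromosome X, 140539528 to 140600659), rose from 73.2 ± 32.1 to 137 ± 52.1 (log2 0.94, SE 0.139; adjusted p = 0.00045). Of 13 glucocorticoid response genes 6 rose, or 10 adjusted over the list alone, and none fell, with Per1 at 0.93 (adjusted p = 0.0074; 0.189 with voom weights and 0.394 without a time term, the highest over its alternatives). The list's median was 0.45 (adjusted p = 1.5e-08; adjusted p = 0.0415 with an estimated correlation). The library mean of the 8 mature neutrophil genes tested was 1.03-fold (permutation adjusted p = 0.490). Under the filter, and so not tested, were Ly6g at 0.53 with IgG and 0.63 with anti-Ly6G, S100a8 at 0.315 and 0.97, and S100a9 at 0.491 and 1.27.

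Of 12504 genes tested in liver, 97 rose and 78 fell, with 4 rises above 2-fold. Lcn2, an iron-binding acute phase gene, rose from 4.19 to 18.8 (log2 1.48, SE 0.358; adjusted p = 0.0271), and the metallothionein genes Mt2 (1.33; adjusted p = 0.0253) and Mt1 (1.21; adjusted p = 0.0253) rose with it, all at 6 of 6 ZT. The Mt1 and Mt2 calls ended without ZT 5, 13 or 21, with adjusted p up to 0.179, and the Lcn2 call ended without each ZT but 9, up to 0.109, and without anti-Ly6G replicate 10 (0.0506). Of 16 acute phase genes 3 rose, or 8 adjusted over the list alone, with a median of 0.30 (adjusted p = 3.5e-09; adjusted p = 0.439 with an estimated correlation). The acyltransferase gene Acnat2 rose by a log2 of 0.83 and the adhesion gene Vcam1 by 0.60. The tissue factor gene F3 fell to -0.51, the Wnt receptor gene Fzd8 to -0.48 and Gpr146 to -0.43. None of 16 macrophage genes passed over all genes, and 7 were higher adjusted over the list alone. Their median was 0.28 (adjusted p = 2.1e-08; adjusted p = 0.448 with an estimated correlation), with Marco at 0.59 and Cd5l at 0.48. Of 11 immediate early genes Junb (-0.43) and Ier2 (-0.32) fell (list adjusted p = 0.020; adjusted p = 0.448 with an estimated correlation), and both calls ended without ZT 1, 9, 13 or 21, with adjusted p up to 0.145. The liver count was 108 and 106 without anti-Ly6G replicates 4 and 10, 115 without IgG replicate 12, 12 without a time term, 287 with array weights, and 48, 81, 63 and 89 without ZT 5, 9, 13 and 21. Of 11417 genes tested in both tissues, 15 rose in bone marrow and liver, against 8.70 if the calls were independent, and 4 fell in both, against 4.50.

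Liver rhythms were large in both treatments. Dbp peaked at 8.59 h (SE 0.367, 97.6-fold) with IgG and 7.84 h (SE 0.428, 51.0-fold) with anti-Ly6G, and Arntl at 21.0 h (13.7-fold) and 20.2 h (13.5-fold). Nr1d1 peaked at 6.20 and 5.31 h and Cry1, a repressor of the clock, at 18.8 and 17.4 h. The mitochondrial unfoldase gene Clpx peaked at 21.9 h (6.61-fold) and 21.1 h (4.70-fold), the bile salt export pump gene Abcb11 at 0.623 and 0.485 h, and the fatty acid elongase gene Elovl3 at 22.3 h (19.5-fold) and 21.5 h (18.6-fold). All 19 core clock genes were rhythmic with IgG, and 18 were with anti-Ly6G, where Bhlhe40 was not (adjusted p = 0.247). With IgG 5368 genes were rhythmic and with anti-Ly6G 4333, of which 3211 were shared, against 1860.2 if independent. The deubiquitinase gene Uchl5 was the only gene with a differential rhythm (adjusted p = 0.045), with an amplitude of 0.05 with IgG and 0.28, peaking at 11.3 h, with anti-Ly6G. The number of such genes was between 0 and 2 when 1 library was left out, and differed from 1 for 31 of 36 libraries. It was 0 without ZT 1, 17 or 21, 3 without ZT 9, and 0 with no filter or with a robust trend.

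In lung, the clock genes cycled with large folds at other hours than in the tissues above, going by the labelled ZT and treatment. Both labels are in doubt, so differences between IgG and anti-Ly6G in this paragraph may not be those of the treatments. Dbp peaked at 3.44 h (SE 0.404, 70.5-fold) with IgG and at 0.301 h (SE 0.41, 66.7-fold) with anti-Ly6G. Arntl peaked at 16.7 h (SE 0.388, 15.1-fold) and 13.5 h (SE 0.414, 12.7-fold), and Nr1d1 at 1.92 h (53.0-fold) and 23.5 h (35.8-fold). All 19 core clock genes were rhythmic with IgG and 16 with anti-Ly6G, or 19 and 17 adjusted over the list alone, with Per1 (adjusted p = 0.356), Ciart (0.236) and Cry2 (0.123) the exceptions. Outside the clock, the Notch pathway gene Dtx4 peaked at 15.9 h with IgG and 12.9 h with anti-Ly6G, and the cell cycle phosphatase gene Cdc25b at 2.40 h with IgG. A differential rhythm was called for 8 genes, all at adjusted p = 0.0471, 3 of them among the 19 core clock genes, of which 13 passed adjusted over the list alone. The clock genes Arntl, Nfil3 and Bhlhe41 peaked at 16.7, 15.5 and 4.51 h with IgG and at 13.5, 12.0 and 0.505 h with anti-Ly6G. The chaperone genes Hyou1 and Sdf2l1 of the endoplasmic reticulum peaked at 15.8 and 17.1 h with IgG and at 11.6 h each with anti-Ly6G, and Acsf2, Zfp346 and 5330417C22Rik were the others. Rhythmic genes numbered 1759 with IgG and 1986 with anti-Ly6G, of which 774 were shared, against 223 if independent. The lung IgG rhythmic count was 847, 976, 969 and 1159 without ZT 1, 9, 13 and 21, and the anti-Ly6G count was 603, 859 and 639 without ZT 1, 9 and 21. The number of differential rhythms was between 0 and 30 when 1 library was left out, moving by more than 1.5-fold for 32 of 36 libraries, and was 216 without ZT 17, 18 without ZT 5, 1 without ZT 1 and 0 without ZT 21.

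**Figure D2:**
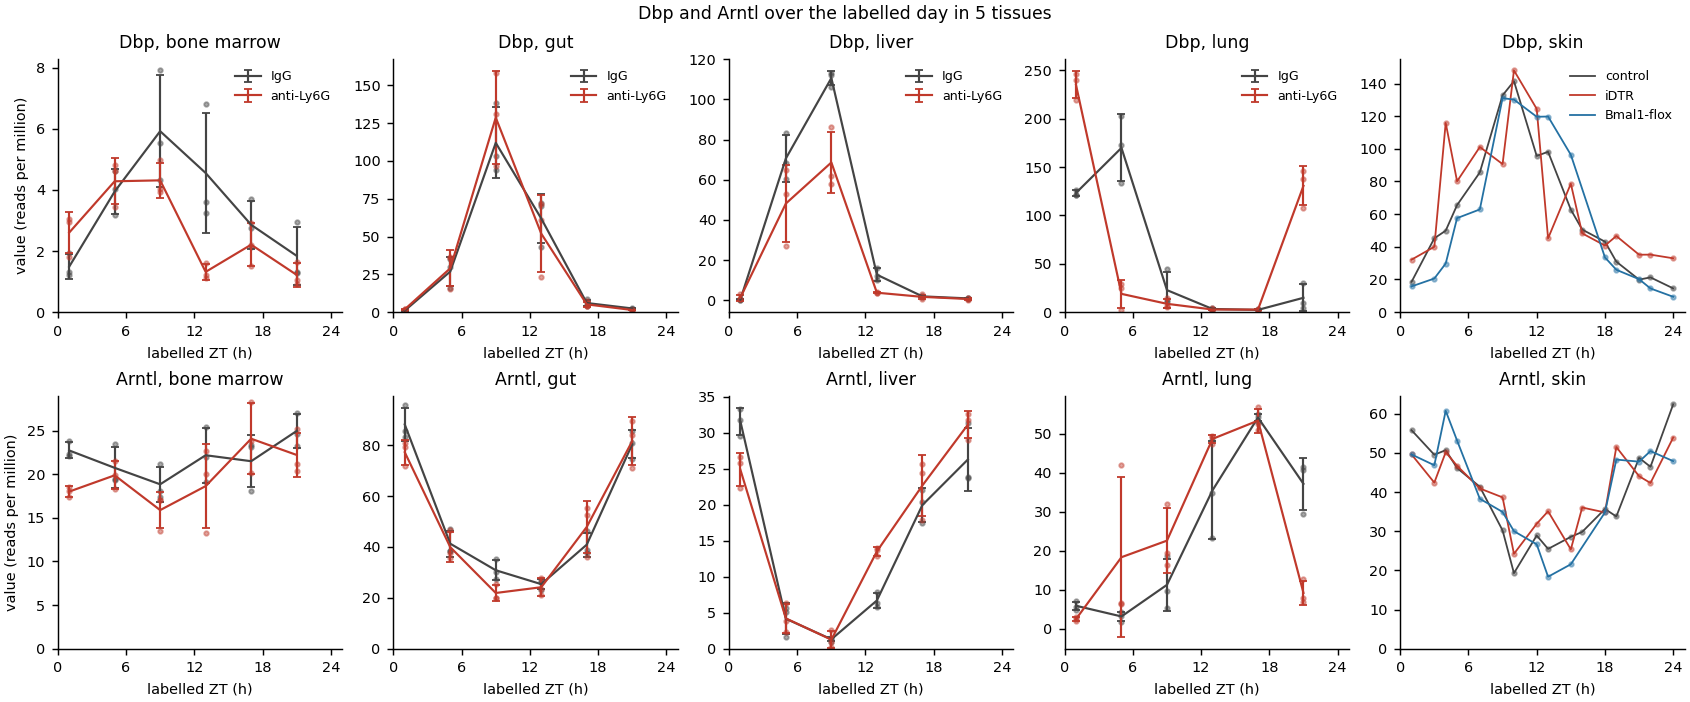
Values of Dbp and Arntl (vertical axes, normalized signal) against labelled ZT in hours (horizontal axis) in the 5 tissues, with a point per library. Lines join means with SD of 3 libraries in the antibody tissues and single libraries in skin, and in lung with IgG Dbp peaked at 3.44 h against 8.59 h in liver.

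Treatments of lung libraries go by their labels, which are in doubt, as most title numbers carry the other treatment in liver. The direction of each lung difference between treatments, above and below, is therefore in doubt too. Between treatments no lung gene passed in limma, with 1462 of 15641 at an unadjusted p under 0.05, a lowest adjusted p of 0.122 and 0 genes by voom weights. The count was 1 without anti-Ly6G replicate 14, without IgG replicate 11, without ZT 5 or without ZT 9, and 2 without ZT 13. Mitotic genes had a median of 0.19, and 10 of 16 were higher adjusted over the list alone, with Mki67 at 0.37 and Cdk1 at 0.29 (adjusted p = 9.4e-13; adjusted p = 0.199 with an estimated correlation). B cell genes had a median of 0.26 and 2 of 11 were higher adjusted over the list alone, with Cd22 at 0.35 (adjusted p = 6.0e-05; adjusted p = 0.448 with an estimated correlation). Erythroid genes had a median of 0.70, with Hba-a1 at 0.76 (adjusted p = 0.010; adjusted p = 0.487 with an estimated correlation). Glucocorticoid response genes had a median of -0.28, and 4 of 13 were lower adjusted over the list alone, with Per1 at -0.69 and Tsc22d3 at -0.64 (adjusted p = 0.0028; adjusted p = 0.487 with an estimated correlation). The library mean of 14 mature neutrophil genes was 1.09-fold and that of 11 specific granule genes 1.13-fold with anti-Ly6G (permutation adjusted p = 0.0608 and 0.05995; 0.03895 and 0.0447 with a pseudocount of 5).

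In skin, iDTR mice given DT were compared with mice given DT and labelled wild-type, to ask what DT did in mice that carry its receptor. Whether the changes followed from a loss of neutrophils or of other cells with the receptor was not tested. Genes of lipid synthesis and the sebaceous gland fell by large folds. Fa2h, which hydroxylates fatty acids of skin lipids (ENSMUSG00000033579, chromosome 8, 111345135 to 111393824), fell from 1236 ± 218 to 18.3 ± 9.22, 69.9-fold lower (log2 -6.13, SE 0.149; adjusted p = 9.2e-36; n = 16 each). Krt6a, a keratin of stressed and wounded epidermis (ENSMUSG00000058354, chromosome 15, 101689910 to 101694307), rose from 108 ± 34.9 to 1584 ± 403, 14.6-fold higher (log2 3.87, SE 0.174; adjusted p = 1.2e-24). Both held at 16 of 16 ZT. All 8 specific granule genes of neutrophils rose, with a library mean 2.33-fold higher (4.18 ± 0.323 against 2.96 ± 0.321; permutation adjusted p = 9.3e-05).

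All 12 fatty acid synthesis genes fell, among them Scd1 (7199 to 569.7, log2 -3.73) and Elovl6 (1182 to 104, log2 -3.50), with a median of -1.35 (adjusted p = 4.5e-11; adjusted p = 0.0415 with an estimated correlation). All 12 sebaceous gland and adipocyte genes fell, with the sebaceous receptor gene Mc5r at -2.54 (median -1.16, adjusted p = 3.1e-08; adjusted p = 0.0415 with an estimated correlation). After Fa2h, the largest falls were in Elovl3 (297 to 4.80, log2 -5.86), Acoxl (-5.34), Serpinb6d (-5.29), Far2 (fatty alcohol synthesis, -5.23), Panx3 (-5.15), Serpina3b (-4.74) and Awat1 (wax synthesis, -4.66). Of 18 cholesterol biosynthesis genes 14 fell and 2 rose (adjusted p = 3.5e-07; adjusted p = 0.448 with an estimated correlation). The largest rises included the immediate early gene Egr4 (0.141 to 110.4, log2 6.11), Sprr2a2 of the cornified envelope (4.38), Krt16 (3.96), and the chemokine genes Ccl20 (4.29) and Cxcl1 (3.54), which attract lymphocytes and neutrophils. Of 12 inflammatory cytokine and chemokine genes 11 rose, with Ccl2 at 2.82 (adjusted p = 1.8e-06; adjusted p = 0.348 with an estimated correlation). All 16 DNA replication genes rose, with Mcm5 at 1.25 (adjusted p = 2.7e-08; adjusted p = 0.439 with an estimated correlation), and all 16 mitotic genes rose, with Top2a at 1.22 (adjusted p = 3.3e-06; adjusted p = 0.577 with an estimated correlation). Of 17 interferon response genes 13 rose, with Cxcl10 at 1.82 (adjusted p = 0.0119; adjusted p = 0.719 with an estimated correlation). Of 12 fibroblast and matrix genes 9 fell, with Col3a1 at -1.49 and Col1a1 at -1.48 (adjusted p = 0.0032; adjusted p = 0.639 with an estimated correlation), and all 9 cartilage genes fell, with Col9a1 at -1.54 (adjusted p = 0.0042; adjusted p = 0.530 with an estimated correlation).

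Among neutrophil genes in skin, S100a9 rose from 5.96 to 18.5 (log2 1.34, SE 0.345; higher at 13 of 16 ZT), Lcn2 by 2.55 and Chil3 by 2.33, at least the last 2 also being made by epithelium and macrophages. The specific granule list passed at adjusted p = 0.00125 (adjusted p = 0.261 with an estimated correlation). Of 13 mature neutrophil genes 8 rose and 4 fell (adjusted p = 0.353), with a library mean 1.52-fold higher (permutation adjusted p = 0.00056), so neither list showed a loss of neutrophil transcripts in iDTR skin. With members also made by other cells, the lists cannot tell whether neutrophils were lost there. The azurophil list had 2 of 4 genes fallen, Ctsg at -0.62 and Nkg7 at -0.43, with a library mean of 0.878-fold (permutation adjusted p = 0.0111; 0.350 after quantile normalization). Of 15946 genes tested, 4886 rose and 5162 fell, with 275 rises and 299 falls above 2-fold. Of 19 core clock genes 8 rose and 7 fell, with Nr1d1 at 1.28, Bhlhe40 at 0.99 and Per3 at -0.76. Medians and means of the core clock list were positive, at 0.09 and 0.11, and its test was not past (adjusted p = 0.979).

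**Figure D3:**
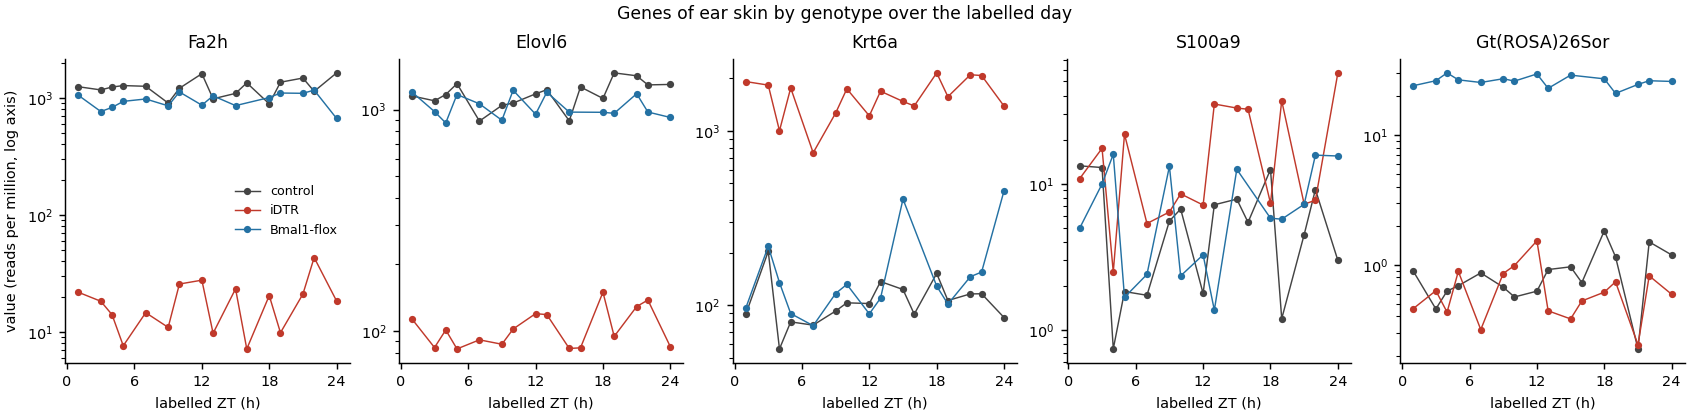
Values of Fa2h, Elovl6, Krt6a, S100a9 and Gt(ROSA)26Sor in skin (vertical log axes, normalized signal) against ZT in hours (horizontal axis), with a point per library colored by genotype. Fa2h had a mean of 1236 in control and 18.3 in iDTR, and Gt(ROSA)26Sor a mean of 0.87 in control and 26.2 in Bmal1-flox.

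The Bmal1-flox skin was compared with the same controls, to ask what loss of the neutrophil clock gene did. Arntl itself (ENSMUSG00000055116, chromosome 7, 113207465 to 113314126), the floxed gene, had a mean of 39.6 ± 12.3 in control (n = 16) and 40.6 ± 12.5 in Bmal1-flox (n = 15; log2 0.01, SE 0.0748; adjusted p = 0.972). The transcript Gt(ROSA)26Sor, from a locus widely used to insert transgenes (ENSMUSG00000086429, chromosome 6, 113067428 to 113077333), was at 0.87 in control and 26.2 in Bmal1-flox, 14.8-fold apart (log2 3.89, SE 0.0894; adjusted p = 1.6e-35; 15 of 15 ZT). It was at 0.655 in iDTR skin, and with IgG at 20.4 in bone marrow, 30.1 in gut, 22.9 in lung and 6.82 in liver, so control and iDTR skin were the low ones, which went against the wild-type label of the control mice. Trim12a, of the TRIM antiviral family (ENSMUSG00000066258, chromosome 7, 104299894 to 104315466), fell from 11.6 to 0.504 (log2 -3.08, SE 0.0845; adjusted p = 2.6e-32). Its neighbours of the family Trim34a, Trim30d and Trim5 fell too, to -1.76, -1.29 and -1.22. Skint9, Skint3 and Skint4, related to butyrophilins, rose by 4.59 (10.1 ± 21.5 to 77.7 ± 35.5; 14 of 15 ZT), 3.86 (4.28 ± 9.63 to 34.0 ± 16.1) and 3.19 (3.79 ± 7.07 to 27.4 ± 12.8), with wide spreads between control mice.

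Of 15946 genes 385 rose and 512 fell, with 14 rises and 28 falls above 2-fold. Other large changes were rises of Cyp2g1 (1.41) and the water channel gene Aqp5 (1.32), and falls of the interferon-induced GTPase gene Gvin1 (-2.15) and of Kbtbd12 (-1.97). Of 9 erythroid genes 2 rose, or 5 adjusted over the list alone, Hba-a1 at 1.45 and Hba-a2 at 1.44 (list adjusted p = 0.039; adjusted p = 0.577 with an estimated correlation), and these calls ended without 2 and 23 of the 47 libraries left out singly. Of 10 endothelial genes 2 fell, or 4 adjusted over the list alone, with Vwf at -0.30 (adjusted p = 0.0024; adjusted p = 0.487 with an estimated correlation). Of 18 cholesterol biosynthesis genes 4 fell and 1 rose, or 8 and 1 adjusted over the list alone (adjusted p = 0.020; adjusted p = 0.763 with an estimated correlation). Of 12 keratinocyte genes Flg, encoding filaggrin, rose by 0.59 (adjusted p = 0.020; adjusted p = 0.487 with an estimated correlation). Library means of the mature, specific and azurophil lists were 1.09-, 1.09- and 0.981-fold (permutation adjusted p = 0.199, 0.377 and 0.552). Of 138 genes tested within 10 Mb of Arntl 35 were called, or 25.4% against 5.45% of the other genes (Fisher's exact p = 2.4e-14). Chromosome 7 held 182 called genes, against 72.5 from its share of tested genes. Calls were dense away from Arntl too, with 22.1% of 163 genes from 40 to 60 Mb of chromosome 7 and 19.05% of 168 from 40 to 60 Mb of chromosome 11. The 28.9% of 142 genes called from 80 to 100 Mb of chromosome 7 adjoined the dense stretch around Arntl.

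**Figure D4:**
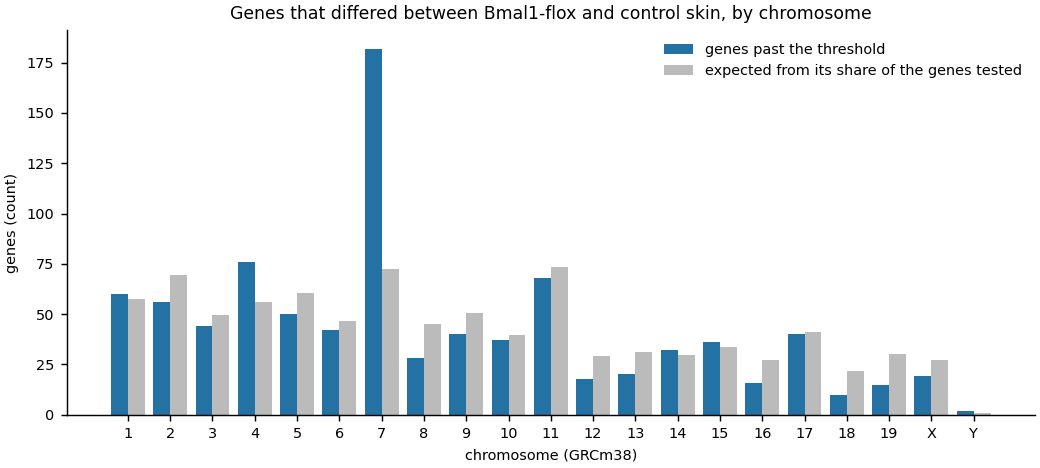
Number of genes called between Bmal1-flox and control skin per chromosome (horizontal axis) beside the number its share of tested genes would give (vertical axis, genes). Chromosome 7, which carries Arntl, had 182 called genes against 72.5.

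Set directly against Bmal1-flox skin, iDTR skin differed in 4860 genes that were higher and 4944 that were lower. Fa2h was at log2 -5.76 (SE 0.151; adjusted p = 3.6e-34), Elovl3 at -5.40 and Far2 at -5.05, while Egr4 was at 6.06, Ccl20 at 3.97 and Krt6a at 3.42. Fatty acid synthesis (12 of 12 lower; adjusted p = 1.3e-12) and sebaceous gland and adipocyte genes (12 of 12 lower; adjusted p = 3.0e-08) passed also with an estimated correlation, at adjusted p = 0.0073 and adjusted p = 0.0117 with an estimated correlation. The library mean of the specific granule list was 2.13-fold and that of the mature list 1.39-fold in iDTR (permutation p = 3e-05 and 0.00033, not adjusted), while that of the azurophil list was 0.895-fold (permutation p = 0.0357, not adjusted).

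Rhythms in skin rested on 1 mouse per ZT and genotype. Dbp peaked at 10.3 h (SE 0.309, 6.50-fold) in control, 9.36 h (SE 0.475, 3.36-fold) in iDTR and 11.3 h (SE 0.269, 10.1-fold) in Bmal1-flox. Arntl peaked at 0.733 h (2.23-fold), 0.693 h (1.66-fold) and 1.26 h (2.31-fold; adjusted p = 2.6e-06) in that order. Each genotype had 14 of 19 core clock genes rhythmic with the shared spread, and with its own spread control had 14, iDTR 4 and Bmal1-flox 14. Arhgap20 and Spon2 peaked at 2.45 and 3.34 h in control and at 2.66 and 3.17 h in Bmal1-flox, and the alarmin gene Il33 at 3.10 h in Bmal1-flox. In iDTR the 6 smallest p-values outside the clock, with the shared spread, were those of Rrm1 (peak at 20.8 h, 2.02-fold), Smc2 (21.4 h, 2.14-fold), Incenp (22.4 h, 2.26-fold), Fanca, Tfrc and Adh1. In control 61 genes were rhythmic, in Bmal1-flox 52 and in iDTR 1731. Control and iDTR shared 22, against 6.62 if independent, and control and Bmal1-flox 21, against 0.199. The iDTR count was 1130 without iDTR replicate 3 and 15 with the spread of the iDTR libraries alone. With array weights the control count was 126 and the Bmal1-flox count 139.

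A differential rhythm between iDTR and control was called for 23 genes, none of them in the core clock list, where 3 of 19 genes passed adjusted over the list alone. The 8 smallest p-values were at adjusted p = 0.0409 each. The cyclin genes Ccnb1 and Ccnb2 and the cytokinesis gene Cep55 had amplitudes of 0.10, 0.23 and 0.16 in control and 0.68, 0.74 and 0.60 in iDTR, where they peaked at 21.6, 22.0 and 22.2 h. Cotl1, Cpxm1, Lrrc17, Sema3e and Rpl23a-ps3 had the other smallest p-values. The count was between 0 and 251 when 1 library was left out, moved by more than 1.5-fold for 33 of 47 libraries, and was 0 with voom weights or no filter, 285 with array weights and 41 with a pseudocount of 5. Between Bmal1-flox and control no gene passed in limma, with 563 at an unadjusted p under 0.05 and 0 by voom weights. The smallest p-values, not past, were those of Baiap2l1, Gm37404 and Gm27029 (adjusted p = 0.999 each).

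The timing of the core clock as a whole was compared last, by a permutation test chosen after the data were seen. With anti-Ly6G the core clock genes peaked earlier than with IgG, in a mean weighted by amplitude, by 2.85 h in bone marrow (permutation adjusted p = 0.00021), where the mean took in 18 genes and 6 were rhythmic with IgG and 8 with anti-Ly6G, and by 0.579 h in gut (0.0468) and 0.873 h in liver (0.0104). In lung the difference was 2.91 h (0.00012), going by the labelled ZT and treatment, which are both in doubt there. In skin, iDTR differed from control by -0.548 h (adjusted p = 0.501; -0.736 to -0.201 h with 1 library left out, the latter without iDTR replicate 1) and Bmal1-flox by 0.701 h (adjusted p = 0.191). Measured against liver with IgG, the mean offset of the core clock genes was 1.38 ± 1.06 h in gut with IgG, 0.577 ± 1.11 h in bone marrow with IgG, 1.54 h in control skin, and -5.50 ± 2.99 h in lung with IgG.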

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

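The lung tests, the odds ratio near Arntl as a test of DT, the windows of chromosomes 7 and 11, the line over title numbers the fit with the spread of iDTR libraries alone and the groupings with group means removed were chosen after their results, or those of the tests they replace, were seen. The other groupings and the other tests in this part were not.

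Some results stand out because an effect on rhythms, or in the last case a level, differed between groups by its own test. In bone marrow 1 gene, Nr1d2, had a differential rhythm, and of 100 drawn groupings, the labelled one included, 3 gave as many (1 as the highest other), where exchanged level differences add waves, and with group means removed 1 did (0 as the highest other), which excludes chance in these draws. In liver 1 gene, Uchl5, had a differential rhythm, and 2 of 100 groupings gave as many, with 1 as the highest other, a share under 0.05. Another grouping thus gave the same count, and the count moved for 31 of 36 libraries left out singly, so chance is not firmly excluded. In lung 8 genes had a differential rhythm, and 1 of 100 groupings, the labelled one, gave as many, with 1 as the highest other, but an earlier set of draws held a grouping with several times the labelled count, so chance is not firmly excluded. In iDTR skin 23 genes did, and 28 of 100 groupings gave as many (6500 as the highest other), which is no reference because exchanged level differences add waves. With group means removed 3 did, a share under 0.05, but another grouping gave 89, so chance is not firmly excluded. A structure of the samples was not tested. Between iDTR and Bmal1-flox skin 9804 genes differed, and 1 of 100 groupings, the labelled one, gave as many, with 5815 as the highest other, so chance is excluded.

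The first pattern is the timing of the lung clock, whose core genes lay -5.50 h from liver with IgG and -8.22 h with anti-Ly6G. An effect of anti-Ly6G alone does not account for it, since both groups lay over 5 h away and, whether the labels or the title numbers give the treatment, 1 of these groups received mostly IgG. A candidate explanation is that lung libraries carry the time of another library, since the ZT of the liver library with the same title number, which differs from the labelled ZT for 36 of 36 libraries, let a 24 h wave explain 77.7% of the variance of 19 core clock genes and moved their mean offset from -6.91 to -0.945 h. The labelled ZT explained 56.9%, the best of the 10000 random reassignments 34.5%, and the labelled ZT in liver 71.5%, and as the title numbers move most anti-Ly6G libraries by more hours than IgG ones, and carry the other treatment in liver for most of them, the lung differences between treatments are in doubt too. A lung clock with another phase and correct labels was argued against over the anti-Ly6G libraries alone, where a move shared by all changes nothing. There the title number's ZT explained 81.2% against 58.4%, a gain of 22.9 points (6.30 to 24.5 with 1 library left out, 19.01 at most in 10000 random orders of the same moves). No random orders were drawn with a library left out, so the margin over them may rest on 1 library. The test replaced an undecided one of the spread within ZT (up to 3.04 times the liver median with libraries numbered 1 to 3, 1.801 at IgG ZT 9 without them). Lung values are still given by their labels, which run 3 by 3 along the titles sorted as text.

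The second pattern is the count of rhythmic genes in iDTR skin, 1731 against 61 in control, where 8 of 100 groupings gave as large a difference (3901 as the highest other) with the level differences left in, which is no reference. With group means removed 1 did, the labelled one (1356 as the highest other). Exchanged labels put the more variable iDTR mice in both groups, so this test cannot exclude a chance excess from unequal spread. Part of the higher count may come from iDTR mice varying more between themselves than the shared spread allows. With the spread of each group alone the counts were 15 in iDTR, 72 in control and 81 in Bmal1-flox. The residual SD was 0.194 in iDTR and 0.161 in control. Core clock genes called in iDTR also went from 14 to 4, so this fit removed known rhythms too. With ZT exchanged within iDTR, which keeps its spread and the shared fit, 1 of 100 groupings, the labelled one, gave as many as 1731. The highest other gave 1047 and the median was 0, so in these draws unequal spread alone did not reach the count. With each library's position along the difference between iDTR and control as a covariate, iDTR kept a count of 809 and control 58. With a line over the title numbers they were 72 and 78, with 7 core clock genes left in iDTR where the prediction required 8. An uneven reaction to DT in iDTR mice and one that grows through the collection cannot be told apart from a daily wave with 1 mouse per ZT. A rhythm brought about by a loss of neutrophils, a loss that the mature and specific granule lists did not show but could not decide, stays open, as untested.

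The third pattern is the genes that differ between Bmal1-flox and control skin, with Arntl itself at 40.6 and 39.6. Chromosome segments of another strain carried with the engineered alleles may account for part of them, since genes within 10 Mb of Arntl were called 4.65 times as often as the others. Chromosome 7 held 182 called genes against 72.5 and chromosome 4 held 76 against 55.8. The clusters were not tied to Arntl alone, as 36 of 163 genes were called from 40 to 60 Mb of chromosome 7 and 32 of 168 from 40 to 60 Mb of chromosome 11. The 41 of 142 genes called from 80 to 100 Mb of chromosome 7 adjoin the dense stretch around Arntl (44 of 157 from 100 to 120 Mb), so they may belong to it. The DT given to the control and not to the Bmal1-flox mice was taken not to act by position, and so to leave at most a small excess near Arntl. The lower 95% limit of the odds ratio there was 3.87. This ratio restates the excess, and genes of a family, such as Trim12a and its neighbours, lie together there, so it does not decide on DT. For the called genes elsewhere too, DT cannot be told apart from genotype, since both change together. That 396 of the 897 also differed from iDTR in the same direction decides nothing, because both differences share the Bmal1-flox libraries and 9804 genes differ between iDTR and Bmal1-flox. An effect of the neutrophil clock stays open, as untested.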

How the results depend on the processing

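Voom weights, the log2 without a pseudocount, the fits without the high-muscle marrow library, the 2 gut libraries with transcripts of other organs or lung libraries 1 to 3, and the list means after quantile normalization or with pseudocounts of 0.1 and 5 were chosen after the data were seen. Of 375 counts of called genes recomputed over 24 results, 292 stayed within 1.5-fold and 83 moved. Of 12775 values of named genes, 12353 stayed on the same side of the threshold, 350 fell short of it and 72 passed it anew. None reversed its direction with a call in either fit. Direction was compared for differences in level only, and changes of sign without a call were not counted. Fits with 1 library left out are not among these values. List tests are not among these values, and of 246 of them 81 passed with the preset correlation and 3 with an estimated one. The counts that stayed within 1.5-fold under each alternative were those of differences between iDTR and each other genotype and between Bmal1-flox and control, and the 0 differential rhythms of Bmal1-flox, for none of which a ZT was left out, so they faced fewer alternatives than the other tissues. Depth limits genes near 1 unit, where 1 read equals up to 0.131 units.

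With 1 library left out, counts were 2107 to 2747 for bone marrow treatment, 2 to 44 for gut, 106 to 191 for liver, 0 to 1 for lung, 9835 to 10086 for iDTR, 702 to 1044 for Bmal1-flox and 9625 to 9843 between them. Rhythmic counts with IgG and anti-Ly6G were 147 to 359 and 28 to 147 in bone marrow, 4497 to 5227 and 3177 to 3827 in gut, 4937 to 5499 and 3898 to 4414 in liver, and 1336 to 1943 and 1457 to 2453 in lung. In skin they were 41 to 69 in control, 1130 to 2267 in iDTR and 37 to 67 in Bmal1-flox. Differential rhythms were 1 to 1 in bone marrow, 0 to 1 in gut, 0 to 2 in liver, 0 to 30 in lung, 0 to 251 in iDTR and 0 to 0 in Bmal1-flox.

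Leaving out samples moved these counts, some up and some down, and the cause was not tested. Without ZT 1, treatment called 1394 genes in bone marrow and 22 in gut, bone marrow anti-Ly6G had 787 rhythmic genes, lung 847 with IgG and 603 with anti-Ly6G, and differential rhythms were 0 in bone marrow, 0 in liver and 1 in lung. Without ZT 5, treatment called 0 in gut, 48 in liver and 1 in lung, bone marrow had 104 and 33 rhythmic genes, and differential rhythms were 1 in gut and 18 in lung. Without ZT 9, treatment called 1 in gut, 81 in liver and 1 in lung, rhythmic genes were 27 in bone marrow anti-Ly6G and 976 and 859 in lung, and liver had 3 differential rhythms. Without ZT 13, treatment called 16 in gut, 63 in liver and 2 in lung, lung had 969 rhythmic genes with IgG, and bone marrow had 0 differential rhythms. Without ZT 17, bone marrow had 24 rhythmic genes with IgG, and differential rhythms were 0 in liver and 216 in lung. Without ZT 21, treatment called 1 in gut and 89 in liver, bone marrow anti-Ly6G had 7 rhythmic genes, lung had 1159 and 639, and differential rhythms were 0 in liver and 0 in lung. Without the bone marrow anti-Ly6G library with a high skeletal muscle list (replicate 4) that group had 28 rhythmic genes, and without the 3 lung libraries numbered 1 to 3 lung had 44 differential rhythms.

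For the alternatives that follow, the cause was not tested. Array weights gave 568 and 181 rhythmic genes in bone marrow, 3025 in lung anti-Ly6G, 126 in control and 139 in Bmal1-flox skin, 32 treatment calls in gut and 287 in liver, and 79 differential rhythms in lung and 285 in iDTR. With ZT as a factor, rhythmic genes were 396 and 498 in bone marrow and 1050 in lung with IgG, and differential rhythms were 3 in bone marrow, 3 in liver and 173 in lung. With each group fitted alone, rhythmic genes were 153 and 30 in bone marrow, 15 in iDTR and 81 in Bmal1-flox. A minimum range of 0.5 left 92 in bone marrow with IgG, 1575 and 1288 in gut, 2907 and 2170 in liver, 677 and 725 in lung, and 882 in iDTR. No time term gave 0 treatment calls in gut and 12 in liver. A block for replicate number gave 0 in gut, and since 6 of 18 gut pairs of the same number had residuals correlated above 0.1, the numbers do not pair the mice. A stricter filter gave 16 treatment calls in gut and 2 differential rhythms in liver. No filter gave 0 differential rhythms in liver, 0 in lung and 0 in iDTR. A robust trend gave 0 in liver and 0 in lung. Voom weights gave 41 treatment calls in gut and 2 differential rhythms in liver and 0 in iDTR. The log2 without a pseudocount gave 0 differential rhythms in lung and 15 in iDTR, quantile normalization 15 in iDTR and a pseudocount of 5 gave 41. The mean difference of the mature list in bone marrow was 0.11 with a pseudocount of 5 and 0.11 after quantile normalization, both past the threshold, those of the mature and specific lists in lung were 0.0798 and 0.13 with a pseudocount of 5, and that of the azurophil list in iDTR skin was -0.059 after quantile normalization. With an estimated correlation 3 of 246 list tests passed.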

Other observations

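The groupings with group means removed were chosen after the other groupings were seen, and the other tests in this part were not. In bone marrow, 6 of 18 cholesterol biosynthesis genes rose with anti-Ly6G and none fell, with Mvd at 0.30 and Fdps at 0.28 (adjusted p = 0.0023; adjusted p = 0.487 with an estimated correlation). Of 5 acute phase genes 4 rose, with Orm1 at 0.56, the LPS-binding protein gene Lbp at 0.42 and the haptoglobin gene Hp at 0.34 (adjusted p = 0.00012; adjusted p = 0.261 with an estimated correlation). Of 12 monocyte genes 6 rose, with the fibronectin gene Fn1 at 0.33, F13a1 at 0.27 and Ly6c2 at 0.23 (adjusted p = 0.0408; adjusted p = 0.615 with an estimated correlation). Of 12 stem and progenitor genes 4 rose (adjusted p = 0.103), and none of 12 T cell genes or 10 megakaryocyte genes passed. In gut, with no member past over all genes, B cell genes had Ms4a1 at -0.33 and Cd79a at -0.28 (adjusted p = 0.0149; adjusted p = 0.719 with an estimated correlation), and fatty acid synthesis genes had Pnpla3 at -0.25 and Scd1 at -0.23 (adjusted p = 0.0149; adjusted p = 0.439 with an estimated correlation). In lung, going by the labelled treatment, which is in doubt, T cell genes had a median of 0.15 (adjusted p = 0.000133; adjusted p = 0.487 with an estimated correlation). DNA replication genes had one of 0.10, with Rrm2 at 0.26 and Mcm5 at 0.24 (adjusted p = 1.7e-07; adjusted p = 0.342 with an estimated correlation).

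In iDTR skin, 14 of 16 heat shock and protein folding genes rose and 1 fell, with the chaperone gene Hsp90aa1 at 0.94 (adjusted p = 2.1e-05; adjusted p = 0.160 with an estimated correlation). Of 12 hypoxia and glycolysis genes 7 rose, Pgk1 among them (adjusted p = 0.00757; adjusted p = 0.448 with an estimated correlation). Of 18 immediate early genes 11 rose and 1 fell, with Nr4a3 at 2.51 and Egr1 at 1.99 (adjusted p = 0.019; adjusted p = 0.809 with an estimated correlation). Of 9 acute phase genes 5 rose, with Saa3 at 3.34 (adjusted p = 0.0221; adjusted p = 0.577 with an estimated correlation), and the adhesion gene Icam1 rose by 1.91. Of 7 MHC class II genes 6 fell, with the invariant chain gene Cd74 at -0.67 (adjusted p = 0.0256; adjusted p = 0.719 with an estimated correlation). Of 10 stem and progenitor genes 9 fell, with the cytokine receptor gene Flt3 at -0.89 (adjusted p = 0.010; adjusted p = 0.448 with an estimated correlation). Of 12 fatty acid oxidation genes 8 fell and 2 rose, with the lipid droplet gene Plin2 at -1.77 (adjusted p = 0.0256; adjusted p = 0.487 with an estimated correlation).

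Counts under other groupings of the same libraries follow, as the number of 100 groupings, the labelled one included, with a count as large. For treatment it was 1 in bone marrow (2445 genes, 161 as the highest other) and 1 in liver (175 and 1), which excludes chance. In gut it was 2 (2 genes, 10 as the highest other). Another grouping gave a larger count there, so chance is not firmly excluded, and a structure of the samples was not tested. In lung the count was 0, which each of the 100 groupings reaches by construction (1 as the highest other), so this comparison says nothing about chance. For genotype it was 1 for iDTR (10048 and 8829) and 1 for Bmal1-flox (897 and 397), which excludes chance. For rhythms with ZT exchanged it was 1 in bone marrow with IgG (232 and 18), 1 in gut with IgG (5091 and 5), 1 in gut with anti-Ly6G (3725 and 1), 1 in liver with IgG (5368 and 206) and 1 in liver with anti-Ly6G (4333 and 2). It was also 1 in lung with IgG (1759 and 39), 1 in lung with anti-Ly6G (1986 and 329), and 1 each in control (61 and 1), iDTR (1731 and 1047) and Bmal1-flox skin (52 and 2), and each of these excludes chance. In bone marrow with anti-Ly6G it was 2 (58 and 248), and as another grouping gave a larger count, chance is not firmly excluded. The difference between the rhythmic counts of IgG and anti-Ly6G was reached by 16 groupings in bone marrow (174 and 1484), 8 in gut (1366 and 2205), 7 in liver (1035 and 1548) and 92 in lung (-227 and 3440), so chance is excluded in none of them. A structure of the samples behind the high values of other groupings was not tested. In bone marrow exchanged level differences add waves, and with group means removed 27 groupings reached the difference (1311 as the highest other), so chance is not excluded there either. For differential rhythms the counts of gut and Bmal1-flox skin were 0, which each of the 100 groupings reaches by construction (2 and 127 as the highest other, and 0 in Bmal1-flox with group means removed), so these comparisons too say nothing about chance.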
